A study of Mus musculus with 8 samples.

How the data were processed

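Leukocytes carrying the surface marker CD45 were taken from mouse hearts and sequenced in droplets with a 3' end protocol (10x Genomics, version 2 chemistry) that counts unique molecular identifiers (UMIs, tags that mark single RNA molecules). The labels give 8 libraries in 4 groups of 2: wild-type (WT) or ApoE knockout mice, each on chow or on a Western-type high-fat diet (HFD), all aged 14 months by the sample labels, whereas the series text gives the age in weeks and breaks off where it gives the time on the diet. The files deposited by the authors hold raw UMI counts per gene and barcode, with no normalization, and list 27998 genes. Per the submitters' processing notes the genome build was mm10. The counting tool and the rule by which barcodes were kept are not given in the sources used here. The lowest UMI total of a barcode was 1318 to 3133 depending on the library, so low-RNA barcodes had already been removed, at a limit that differed between libraries.

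From the deposited counts, barcodes with fewer than 200 detected genes or over 10% mitochondrial UMIs were left out (262 of 21940), and the 638 barcodes (2.91%) with the highest Scrublet doublet scores were removed, at 0.8% per 1000 barcodes of a library. The remaining 21040 cells were scaled to 10000 UMIs and log-transformed. The 2000 most variable genes within libraries were reduced to 30 principal components and clustered by the Leiden method at resolution 1 on 20 nearest neighbours (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15). Apoe, mitochondrial, ribosomal, immunoglobulin and T cell receptor genes took no part in clustering. Markers of 19 cell types and states were fixed before the data were examined, as were the tests, the gene lists, the rule for naming genes and the other settings tried, except those named last. The thresholds for naming were set after the clusters were seen: at least 3 markers detected in at least 20% of a cluster's cells at 1.5 times the mean over clusters. A cluster of a type other than macrophages, monocytes or dendritic cells was called mixed when its C1qa, C1qb, C1qc and Csf1r counts reached 0.35 of the macrophage level. Monocytes, a single cluster, stood at 0.355 and were exempt, since their own type can express these genes. Clusters that proliferated or had fewer than 3 markers stayed unnamed. Names therefore mean macrophage-like, T cell-like and so on, throughout.

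UMI counts were summed per library and class, since libraries and not cells are the replicates. Macrophages, T cells and dendritic cells had at least 20 cells in each library and were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, its default filter on low counts; R 4.3.3), at a Benjamini-Hochberg adjusted p of 0.05. An additive model gave the average effects of diet and genotype, 4 libraries against 4. A model of the 4 groups gave the comparisons of 2 libraries against 2, with a spread shared over all 8 libraries, and the interaction of genotype with diet. Fold changes are log2 with their standard error (SE), and levels are CPM (UMIs of a gene scaled to a common library total). Cells per class were tested with edgeR over the leukocytes of each library, beside an exact two-sided permutation test. For 30 gene lists, camera (limma 3.58.1) with a preset correlation of 0.01 compared list members with the other genes; an estimated correlation was the alternative. Lists with fewer than 4 tested members were left out.

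Named genes are Apoe and, among genes past the threshold whose libraries did not overlap, the 8 highest and 8 lowest by fold in the additive comparisons and in ApoE knockout on HFD against WT on chow. The number was 5 and 5 in the other macrophage comparisons and 4 and 4 in the other classes, without predicted gene models. Up to 4 members of each list that passed were added, and where no gene passed, the 3 highest and 3 lowest by p. Positions come from the GENCODE M21 annotation of mm10, in which 27645 of the 27998 gene identifiers were found.

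The tests were checked on simulated data drawn from the macrophage means, library sizes and spread, with 200 genes changed. For the average genotype effect, 66.7% of genes changed by 1 on the log2 scale and 98.0% of those changed by 2 were recovered over 10188 genes. For HFD in the ApoE knockout these shares were 30.6% and 79.6% over 10342 genes. Among unchanged genes 15 were called for genotype, 10 for diet and 5 for HFD in the knockout. Genes were drawn independently with no shift shared by a library, so the check does not cover such shifts. No label or file says whether the replicates of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. The labels give no sequencing date or batch. Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors, no filter on low counts, the replicate number as a block, doublets kept, a mitochondrial limit of 20%, resolution 0.5, only the 4 libraries of a comparison, other scalings of class shares and leaving out each library. Added after the data were seen were macrophage changes relative to T cells, offsets for GC content and transcript length, each class without 1 cluster, a common UMI minimum, and the interaction and comparisons of 2 with 2 libraries in T and dendritic cells.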

Results

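The data describe leukocytes of the mouse heart in a study of metabolic stress and heart failure with preserved ejection fraction, in which genetic loss of ApoE (apolipoprotein E, a carrier of cholesterol-rich lipoproteins) was combined with a high-fat, high-cholesterol diet (HFD). CD45-positive cells were profiled in 2 libraries each of wild type (WT) on chow, WT on HFD, ApoE knockout on chow and ApoE knockout on HFD. The 8 libraries held 1214 to 6534 barcodes and 8193016 to 25414976 UMIs, and the median barcode held 3174.5 to 6084 UMIs. After filtering, 21040 cells formed 28 clusters, of which 8 clusters with 13378 cells were macrophage-like.

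Apoe RNA separated the genotypes in every library. Over all barcodes it stood at 18969 to 26153 CPM in the 4 WT libraries and at 10.9 to 41.2 CPM in the 4 ApoE knockout libraries. In macrophages Apoe fell by 9.50 on the log2 scale (SE 0.42, 4 against 4 libraries, edgeR adjusted p = 2.42e-05). T cells, which should not transcribe Apoe, held 345 to 1564 CPM in WT and 0 to 8.42 CPM in the knockout, and the source of this RNA was not tested. The protocol reads the 3' end of transcripts, so these counts show the loss of the transcript's end and not where the allele was altered.

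B cells and monocytes took a larger share of cardiac leukocytes in ApoE knockout hearts. B cells, the antibody-forming lymphocytes, made up 5.11% ± 4.58 (SD, n = 4) of leukocytes in the knockout and 0.702% ± 0.359 (SD, n = 4) in WT. ApoE knockout on chow replicate 1 held 11.8% (exact Clopper-Pearson 95% interval of counting error 10.5 to 13.3) and the other 3 knockout libraries 1.84% to 4.03%; without it the log2 fold was 2.16 (edgeR adjusted p = 0.0310). Monocytes, the blood precursors of many macrophages, made up 5.58% ± 2.56 in the knockout and 1.27% ± 0.809 in WT. The fold was 7.01 for B cells (log2 2.81, SE 0.62, edgeR adjusted p = 0.00949) and 4.60 for monocytes (log2 2.20, SE 0.51, edgeR adjusted p = 0.00949), and the 4 knockout libraries all lay above the 4 WT libraries. The exact two-sided permutation test gave p = 0.0286 for either class, the smallest that 4 against 4 allows, and 0.0762 after adjustment over 8 classes. A cluster of 246 cells with B cell markers, kept apart as mixed by a threshold set after the clusters were seen, was not counted as B cells. In WT it made up 1.26% of leukocytes on chow and 1.31% on HFD, beside 0.861% and 0.543% counted. In the knockout it made up 1.76% and 0.534%, beside 7.28% and 2.93% counted. The size of the B cell fold therefore depends on that threshold. Macrophages made up 47.1% ± 11.9 of knockout and 70.0% ± 7.31 of WT leukocytes, again without overlap between the libraries, but did not pass (edgeR adjusted p = 0.150; exact permutation p = 0.0286). They passed with TMM scaling over the classes (log2 −1.45, edgeR adjusted p = 0.0285) and without ApoE knockout on chow replicate 2 (log2 −0.78, edgeR adjusted p = 0.0344). T cells stood at 9.84% ± 4.91 and 3.81% ± 1.69 (edgeR adjusted p = 0.0795). Unnamed clusters of 1441 cells, led by genes such as Ccl5, Nkg7 and Lck, and of 411 cells, led by Cd3g, Cd3e and Cd3d among others, were not counted as T cells, beside 1096 counted. The size of the T cell difference therefore depends on the rule for naming clusters. Without ApoE knockout on HFD replicate 2 the monocyte call was lost (edgeR adjusted p = 0.0579) and 1 class passed, and without ApoE knockout on chow replicate 2 the number rose to 6. Shares rest on the CD45 sort and on UMI minimums between 1318 and 3133 per barcode; above a common minimum of 3133, which leaves out more lymphocytes, 5 classes passed.

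Diet changed no class share by the edgeR test (0 of 8 classes; 0 by the exact permutation test, smallest p = 0.114 for dendritic cells; 0 at an unadjusted edgeR p under 0.05). Dendritic cells, which present antigen to T cells, stood at 5.89% ± 1.38 on HFD and 4.01% ± 1.27 on chow (SD, n = 4). Group 2 innate lymphoid cells, producers of type 2 cytokines, stood at 7.04% ± 0.952 in ApoE knockout on HFD, 1.99% ± 2.62 in ApoE knockout on chow, 1.12% ± 0.776 in WT on HFD and 1.12% ± 0.210 in WT on chow (SD, n = 2). The 2 knockout chow libraries held 83 and 3 such cells (3.84% and 0.129%). The second had a lowest barcode total of 3133 UMIs, above the median of 2504 UMIs in this cluster. A further 478 cells with their markers were kept apart as mixed, beside the 405 counted. The interaction of genotype with diet passed in 0 classes, and in 2 classes, innate lymphoid cells and NK cells, without ApoE knockout on chow replicate 1. Above the common UMI minimum, B cells passed for diet (log2 −1.99, edgeR adjusted p = 0.0224). Mixed and unnamed clusters, kept apart by a threshold set after the data were seen, took from 15.4% of leukocytes in WT on HFD to 24.3% in ApoE knockout on chow.

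**Figure D1:**
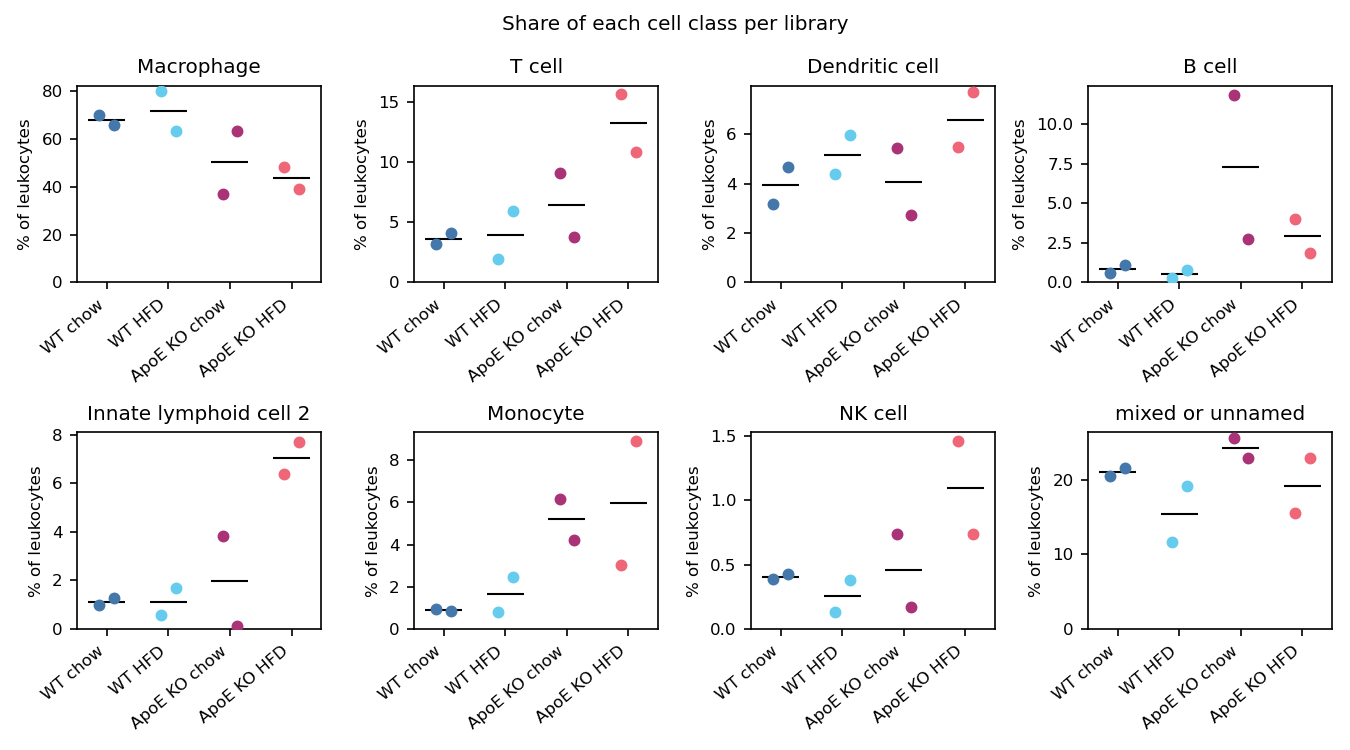
Share of each cell class among leukocytes (y axis, percent) in the 4 groups, with 1 point per library and a bar at the mean of 2 libraries. The B cell and monocyte points of both ApoE knockout groups lie above those of both WT groups.

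Macrophages of the ApoE knockout and WT differed in 11 genes. Apoc1 (log2 3.38, SE 0.26) and Apoc4 (log2 5.55, SE 0.27), lipoprotein genes next to Apoe, and Abcg1 (log2 1.40, SE 0.18), a cholesterol exporter induced by the sterol-sensing receptor LXR, rose in knockout macrophages. Slc40a1, the iron exporter ferroportin, fell by 2.38 (SE 0.19), C5ar2, a receptor for complement C5a, fell by 3.31 (SE 0.43), and Mid1, a ubiquitin ligase on microtubules, fell by 2.87 (SE 0.29). The glycolytic enzyme gene Gapdh rose by 0.95 (SE 0.12), with the interferon-inducible Slfn8 (log2 0.98, SE 0.13) and Rfesd (log2 1.30, SE 0.16), and Prune2 fell by 0.94 (SE 0.13). With Apoe these are the genes, 6 higher and 5 lower, that passed among 10233 by edgeR (4 against 4 libraries, adjusted p from 2.42e-05 to 0.0413), each with no overlap between the genotypes' libraries. DESeq2 called 133.

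Apoe lies on chromosome 7 (19696109 to 19699188, mm10). Apoc1 (19689481 to 19692660), Apoc4 (19678083 to 19681479) and C5ar2 (16234585 to 16244154) lie on the same chromosome, Slc40a1 on chromosome 1 (45908068 to 45926523) and Mid1 on chromosome X (169685199 to 170005736). Apoe, Apoc1, Apoc4, Mid1 and Slc40a1 kept their call without each of the 8 libraries, and the other 6 genes lost it without at least 1. The number of genes was 5 without ApoE knockout on chow replicate 1, without replicate 2 of the same group, without WT on HFD replicate 1 or without its replicate 2. It was 6 without either WT chow library, 7 without ApoE knockout on HFD replicate 2 and 19 without ApoE knockout on HFD replicate 1.

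Averaged over the diets, camera with its preset correlation placed interferon, LXR and lipid-associated genes higher in knockout macrophages, and cholesterol synthesis and resident-macrophage genes lower. Among LXR targets and cholesterol efflux genes, 2 of 12 passed over all genes (Abcg1, and Apoc1 beside the altered Apoe) and 5 rose when adjusted over the list alone (median log2 0.39; camera adjusted p = 3.08e-11, and adjusted p = 0.0165 with an estimated correlation). Cholesterol synthesis and uptake genes had 0 of 18 past the threshold over all genes and 9 lower when adjusted over the list alone (median −0.41; camera adjusted p = 1.88e-08, and adjusted p = 0.0387 with an estimated correlation). Interferon response genes had 0 of 19 and 13 higher adjusted over the list alone (median 0.81; adjusted p = 1.59e-14, but adjusted p = 0.159 with an estimated correlation). Lipid-associated macrophage genes, a program of lipid-laden cells, had 0 of 14 and 6 higher adjusted over the list alone (median 0.33; adjusted p = 0.000365, and adjusted p = 0.0777 with an estimated correlation). Genes of resident macrophages, such as those of Timd4-, Lyve1- and Folr2-expressing cells, had 0 of 15 and 4 lower adjusted over the list alone (median −0.43; adjusted p = 3.93e-05, and adjusted p = 0.225 with an estimated correlation). Monocyte-derived macrophage genes were called higher, with 0 of 10 over all genes and 4 higher and 1 lower adjusted over the list alone. Their median was 0.44 (camera adjusted p = 0.000482, and adjusted p = 0.0636 with an estimated correlation). In the same libraries monocytes made up 5.58% of knockout and 1.27% of WT leukocytes. Camera called 9 of 23 lists, 7 higher and 2 lower, and 3 with an estimated correlation, the third being T and NK effector genes (median 0.73, 0 of 9 over all genes, 2 adjusted over the list alone; adjusted p = 0.0387 with an estimated correlation). These genes mark other cells. In the same libraries T cells made up 9.84% of knockout and 3.81% of WT leukocytes and NK cells 0.777% and 0.329%, without the unnamed clusters led by T or NK cell genes. Without ApoE knockout on HFD replicate 1, 14 lists were called.

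Averaged over the genotypes, HFD moved no macrophage gene past the threshold. Among the nearest was Plin2, the coat protein of lipid droplets, at 276 to 449 CPM in the 4 HFD libraries and 164 to 199 CPM in the 4 chow libraries (log2 1.10, SE 0.15, edgeR adjusted p = 0.136). Mmp9, a matrix-degrading protease, stood at 3.76 to 8.30 CPM on HFD and 16.3 to 27.7 CPM on chow (log2 −1.69, SE 0.23), and Zfp36l2, which promotes mRNA decay, at 90.9 to 144 CPM and 221 to 261 CPM (log2 −0.93, SE 0.12), both at an edgeR adjusted p of 0.136. Copb1 (log2 0.70), Vps35 (log2 0.58) and Metrn (log2 −1.53) did not pass either. The count was 0 of 10233 by edgeR, with 1424 genes at an unadjusted p under 0.05 and 106 called by DESeq2. Without WT on HFD replicate 2 it was 6.

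Camera called 9 of 23 lists for diet, 6 higher and 3 lower, and 0 with an estimated correlation. Interferon response genes stood higher (median log2 0.41, 0 of 19 over all genes, 3 adjusted over the list alone; adjusted p = 8.85e-06, and adjusted p = 0.503 with an estimated correlation), as did NF-kB and inflammatory cytokine genes (median 1.00, 0 of 20, 0 adjusted over the list alone; adjusted p = 8.85e-06, and adjusted p = 0.640 with an estimated correlation). The NF-kB median was 2.16 in the knockout and −0.17 in WT (adjusted p = 0.0571 in WT), and the interferon median 0.97 and 0.09 (adjusted p = 0.670 in WT), so neither list was called in WT. Lipid-associated macrophage genes had a median of 0.20 (0 of 14, 2 adjusted over the list alone; adjusted p = 0.0192, and adjusted p = 0.342 with an estimated correlation). Cardiomyocyte genes, markers of another cell type, were among the 3 lower lists (median −0.45; adjusted p = 0.0242, and adjusted p = 0.653 with an estimated correlation). Without ApoE knockout on HFD replicate 2, 3 lists were called, and without WT on HFD replicate 1, 6.

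In WT mice alone HFD moved no macrophage gene past the threshold. The heat-shock chaperone genes Hspa1b and Hspa1a stood at 74.4 and 80.0 CPM and at 2383 and 2134 CPM on HFD, against 21.3 and 15.6 CPM and 665 and 618 CPM on chow (log2 2.07, SE 0.33, and log2 1.84, SE 0.35; 2 against 2 libraries, edgeR adjusted p = 0.676 and 0.830). Mmp9 (log2 −1.85), Cd209f (log2 −1.75), Man2a1 (log2 1.07) and the immediate early gene Fos (log2 −0.70) did not pass. EdgeR called 0 of 10494 genes, with 614 at an unadjusted p under 0.05 and 6 by DESeq2; without WT on HFD replicate 2 edgeR called 7, and 1 without either ApoE knockout HFD library. The largest share of WT chow macrophages lay in cluster 0 (39.4% and 40.5%), led by the resident-macrophage genes Fcna, Vsig4 and Folr2, whereas on HFD the largest share of replicate 1 lay in cluster 1 (40.1%), led by Hmox1 and heat-shock genes, and that of replicate 2 in cluster 4 (39.9%), led by MHC class II genes. Of 25 lists, 2 were called: cardiomyocyte genes, from cells outside the CD45 sort, with a median of −0.94, and resident-macrophage genes, with 0 of 15 over all genes and 1 lower adjusted over the list alone (median −0.25). With an estimated correlation the adjusted p was 0.501 for both. The number of lists was 8 without WT on chow replicate 1, 6 without WT on HFD replicate 1, 7 without ApoE knockout on chow replicate 2 and 5 without ApoE knockout on HFD replicate 2.

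In ApoE knockout mice HFD went with higher levels of some inflammatory and interferon genes of macrophages. Of the listed genes 11 of 20 and 5 of 19 passed, and with an estimated correlation camera called neither list (adjusted p = 0.298 for both). Ifnb1, which encodes interferon beta, rose from 1.14 and 4.26 CPM on chow to 116 and 79.3 CPM on HFD (log2 5.11, SE 0.65). The interferon-stimulated genes Isg15 (log2 2.30, SE 0.22), Ifit1 (log2 2.17, SE 0.21) and Rsad2 (log2 2.27, SE 0.27) rose, as did the chemokine Ccl4 (log2 2.80, SE 0.49), the inflammasome sensor Nlrp3 (log2 2.53, SE 0.45), the cytokine Il1a (log2 3.55, SE 0.62) and the adhesion molecule Icam1 (log2 1.55, SE 0.23). Plin2 rose by 1.23 (SE 0.20), Lgals3 by 0.70 (SE 0.16) and Cybb, a subunit of the oxidant-producing NADPH oxidase, by 1.10 (SE 0.17). Gas6, a ligand for receptors that clear dying cells, fell by 1.77 (SE 0.21), and the stress genes Hspa1b (log2 −2.49, SE 0.35), Hspa1a (log2 −1.97, SE 0.36) and Dusp1 (log2 −1.23, SE 0.17) fell as well. The stress list as a whole went both ways, with 9 higher and 5 lower of 20 adjusted over the list alone (median 0.41). All named gene changes compare 2 with 2 libraries at edgeR adjusted p from 0.00693 to 0.0475.

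Of 20 NF-kB and inflammatory cytokine genes 11 rose and 9 did not pass, and 19 rose when adjusted over the list alone (median log2 2.16; camera adjusted p = 6.75e-23, but adjusted p = 0.298 with an estimated correlation). Of 19 interferon response genes 5 rose and 14 did not pass, and 12 rose adjusted over the list alone (median 0.97; adjusted p = 3.94e-14, and adjusted p = 0.298 with an estimated correlation). Of the 12 genes listed for B cell activation 3 rose, Bcl2a1b (log2 1.52, SE 0.14), an inhibitor of apoptosis, and the activation markers Cd69 (log2 1.82) and Cd83 (log2 1.48), all of which myeloid cells can express; 9 were higher and 1 lower adjusted over the list alone (adjusted p = 8.35e-08, and adjusted p = 0.298 with an estimated correlation). Among 18 genes listed for reactive oxygen species and antioxidants, Cybb and Slc7a11 (log2 4.52, SE 0.97) passed, 2 in all, and 4 rose adjusted over the list alone. H2-Q6 (log2 1.29) and H2-Q7 (log2 1.14) passed among 12 MHC class I genes, 2 adjusted over the list alone, and Ccnb2 (log2 2.43) among 10 proliferation genes, 4 adjusted over the list alone. Neutrophil genes went both ways: Il1r2 rose by 1.70, whereas S100a8 and S100a9 stood at 0 to 0.415 CPM on HFD and 6.14 to 20.8 CPM on chow. The neutrophil markers, a list of another cell type, were the 1 list called lower. They had 1 higher and 3 lower of 5 adjusted over the list alone (median −1.46, camera adjusted p = 0.0131, and adjusted p = 0.330 with an estimated correlation). Genes of immediate early response and dissociation stress had 0 higher and 3 lower of 20 over all genes, 9 higher and 5 lower adjusted over the list alone (median 0.41; adjusted p = 0.578). Camera called 7 of 25 lists, 4 without WT on HFD replicate 2, and 0 with an estimated correlation.

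Among the 239 lower genes, Scand1 (log2 −5.76, SE 1.03) and Bloc1s4 (log2 −4.67, SE 0.72) fell most among those with over 3 UMIs on HFD, and Zfp771 stood at 0.269 and 0.415 CPM on HFD against 16.8 and 19.7 CPM on chow. In T cells of the same libraries, 148 of the 239 lower macrophage genes were tested and their median was −1.84, beside −1.62 for the same genes in macrophages. For the 57 tested higher genes the medians were 0.36 in T cells and 1.45 in macrophages. In dendritic cells 217 of the lower genes were tested, with a median of −1.63. EdgeR called 362 of 10494 genes, 123 higher and 239 lower, and DESeq2 563. Without either ApoE knockout chow library it called 0, without ApoE knockout on HFD replicate 1 166 and without its replicate 2 1256, and without either WT chow library 188; all 33 genes past the threshold that the naming rule gives lost the call without at least 1 library. Cluster 7, led by Ccl4, Cxcl10 and Ifnb1, held 75.5% of the macrophages of ApoE knockout on HFD replicate 1 and 30.6% of those of replicate 2. On chow the largest shares lay in cluster 4 (46.9% of replicate 1) and cluster 0 (35.7% of replicate 2). Without cluster 7, chosen after the data were seen, 204 genes passed, 42 higher and 162 lower. This left 203 of 830 and 297 of 428 macrophages in ApoE knockout on HFD replicates 1 and 2. Genes that lead the cluster, such as Ccl4, Ifnb1 and Nlrp3, are among those tested, so smaller folds and lost calls follow in part from the choice. Isg15 (log2 1.95), Ifit1 (log2 2.00), Ifnb1 (log2 4.08) and Ccl4 (log2 1.86) kept their call. It was lost by 16 of the 33 named genes, among them Icam1 (log2 1.07), Nlrp3 (log2 1.26), Il1a (log2 1.14), Lgals3 (log2 0.48), Cd69 (log2 1.86), Cd83 (log2 1.18) and Hspa1a (log2 −1.56).

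**Figure D2:**
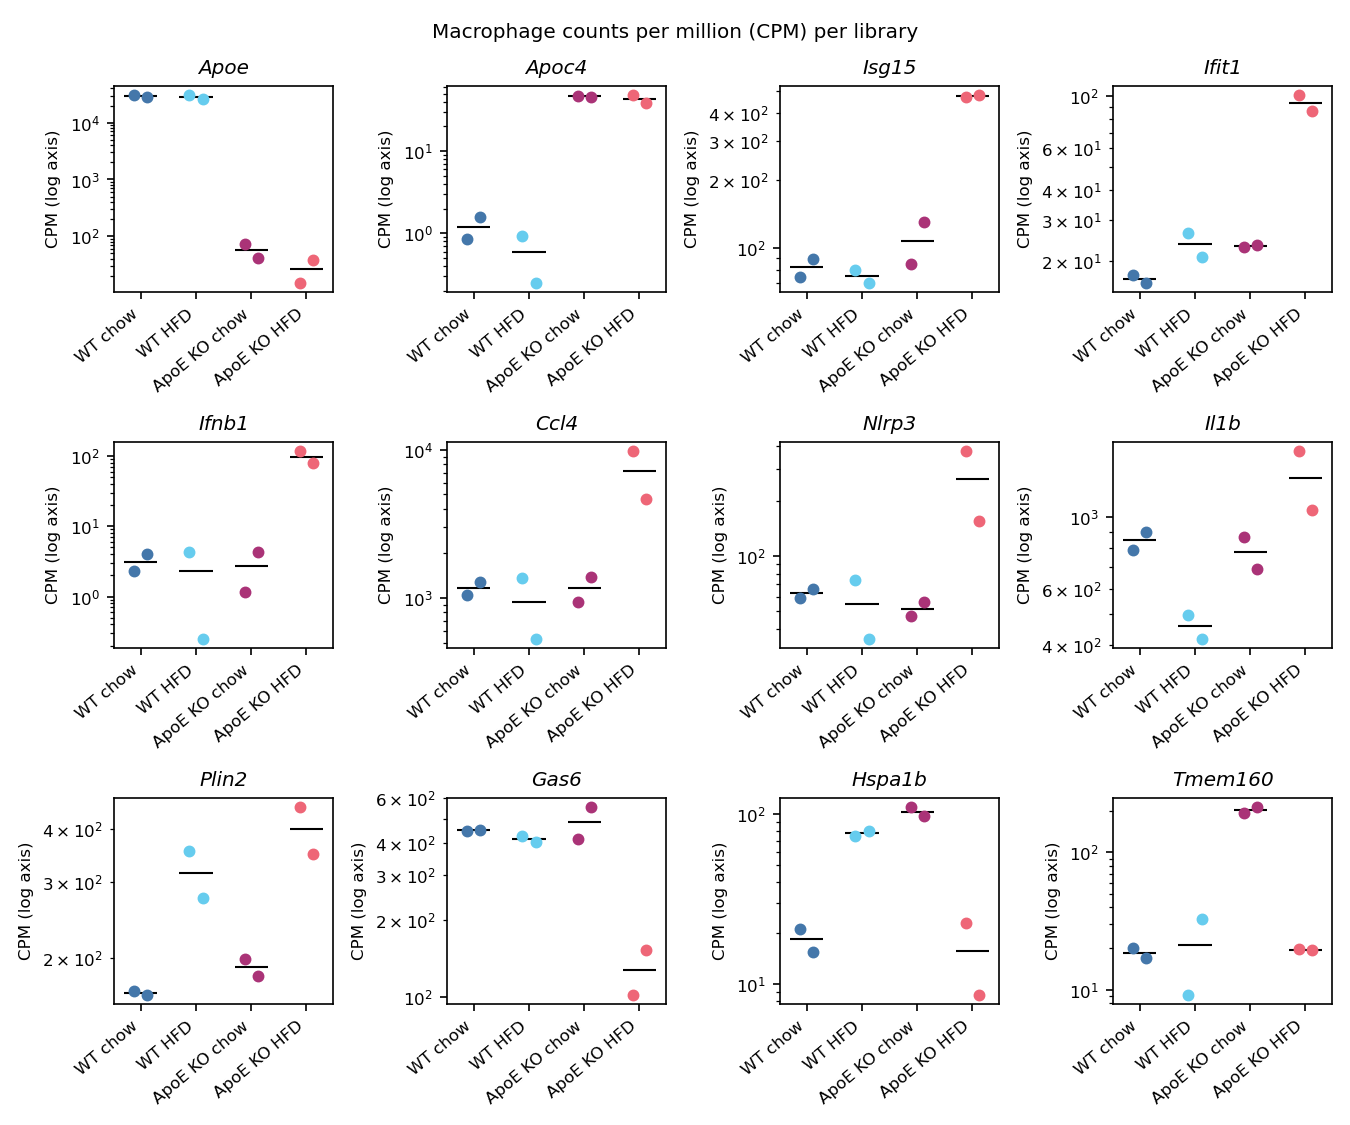
CPM of 12 genes in macrophages (y axis, log scale) in the 4 groups, with 1 point per library and a bar at the mean of 2 libraries; a library at 0 has no point. Ifnb1 stood at 116 and 79.3 CPM in ApoE knockout on HFD and at 0.252 to 4.33 CPM in the other 6 libraries.

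**Figure D3:**
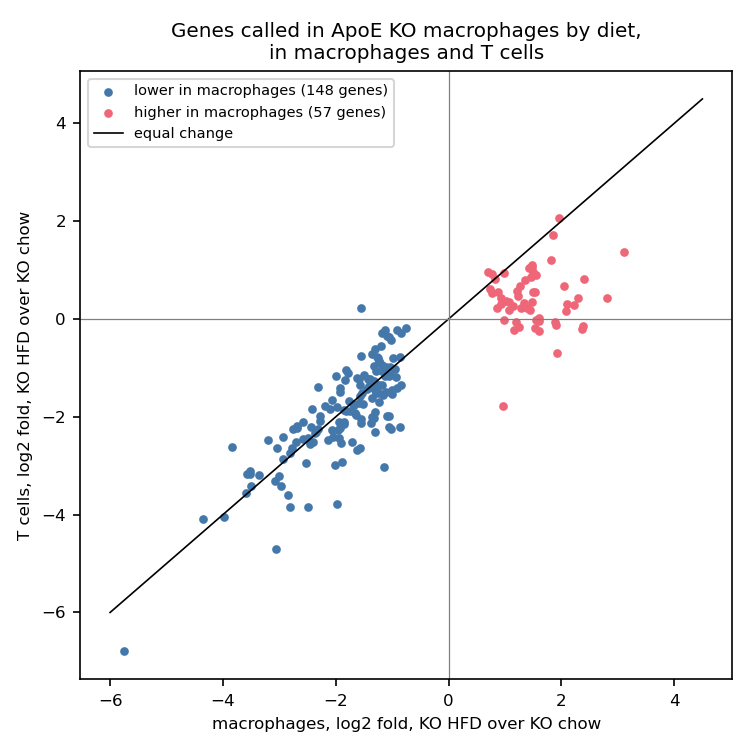
Log2 fold of ApoE knockout on HFD over chow in macrophages (x axis) and T cells (y axis), with 1 point per gene called in macrophages and tested in both. The 148 lower genes lie along the line of equal change, and most of the 57 higher genes lie below it.

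On chow, knockout macrophages differed from WT in 20 genes, among them Apoc1 and Apoc4 beside Apoe. Apoc4 (log2 5.26, SE 0.36) and Apoc1 (log2 3.29, SE 0.39) rose, and Slc40a1 (log2 −2.27, SE 0.26) and Mid1 (log2 −2.78, SE 0.38) fell. Glrx5, a factor of iron-sulfur cluster assembly (log2 3.45, SE 0.44), Tmem160 (log2 3.38, SE 0.43), Hspa1b (log2 2.43, SE 0.33) and S100a9, an abundant neutrophil protein gene (log2 4.66, SE 0.69), rose as well. A cluster with neutrophil markers, kept apart from macrophages, held 65 and 30 cells of the 2 knockout chow libraries and 14 and 8 of the 2 WT chow libraries. EdgeR called 17 higher and 3 lower, at adjusted p from 0.000189 to 0.0428 for those named, and DESeq2 called 107. Fitted on the 4 libraries alone, edgeR called 352. The 10 higher genes tested in T cells had a median of 2.48 there and 2.19 in macrophages. The count was 2 without WT on chow replicate 2 or without ApoE knockout on chow replicate 1, 3 without WT on chow replicate 1 or ApoE knockout on chow replicate 2, 68 without either WT HFD library, 81 without ApoE knockout on HFD replicate 1 and 83 without its replicate 2; Apoe and Apoc4 were called each time. Camera called 13 of 25 lists, 7 higher and 6 lower, and 0 with an estimated correlation. NF-kB genes stood lower (median −0.35, 0 of 20 over all genes, 0 adjusted over the list alone; adjusted p = 0.00997, and adjusted p = 0.742 with an estimated correlation), and LXR targets higher (median 0.34, 1 of 12, namely Apoc1, 2 adjusted over the list alone; adjusted p = 5.70e-06, and adjusted p = 0.110 with an estimated correlation). Cardiomyocyte genes stood lower too (median −0.56; adjusted p = 5.68e-05, and adjusted p = 0.445 with an estimated correlation).

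On HFD, knockout macrophages stood above WT in interferon and inflammatory genes. Isg15 rose by 2.74 (SE 0.23), Ifit1 by 2.05 (SE 0.20), Ifnb1 by 5.06 (SE 0.63) and the T cell-attracting chemokine Ccl5 by 2.58 (SE 0.38). Il1b, the cytokine interleukin-1 beta, rose by 1.63 (SE 0.24) and Ptgs2, the inducible prostaglandin synthase, by 2.77 (SE 0.45). Gas6 (log2 −1.62, SE 0.21), Hspb1 (log2 −3.52, SE 0.46), Nenf (log2 −2.97, SE 0.46) and Yipf4 (log2 −2.55, SE 0.42) fell. All 20 NF-kB genes but 1 were higher adjusted over the list alone, and 4 over all genes (median 1.77; camera adjusted p = 2.46e-27, and adjusted p = 0.126 with an estimated correlation). Of 19 interferon genes 17 were higher adjusted over the list alone and 4 over all genes (median 1.06; adjusted p = 3.19e-25, and adjusted p = 0.0984 with an estimated correlation). The T and NK effector genes, to which Ccl5 belongs, stood higher as well (median 0.79, 2 of 11 over all genes; adjusted p = 0.000129, and adjusted p = 0.0984 with an estimated correlation). T cells, without the unnamed clusters led by T cell genes, made up 13.2% of leukocytes in ApoE knockout on HFD and 3.97% in WT on HFD. EdgeR called 78 genes, 49 higher and 29 lower, with the named genes at adjusted p from 0.000123 to 0.0372, and DESeq2 312; fitted on the 4 libraries alone, edgeR called 3. The count was 21 without either ApoE knockout chow library, 17 without either WT chow library, 9 without WT on HFD replicate 2, 146 without its replicate 1, 51 without ApoE knockout on HFD replicate 1 and 992 without its replicate 2. Apoe, Apoc4, Bcl2a1b, Ifit1, Ifnb1 and Isg15 were called each time. Without cluster 7 edgeR called 25, and 16 of the 26 named genes lost their call. Among these were Ifnb1 (log2 3.85, adjusted p = 0.0520), Bcl2a1b (log2 1.08, adjusted p = 0.0523), Ccl5 (log2 1.20, adjusted p = 0.397), Il1b (log2 1.04, adjusted p = 0.0804) and Ptgs2 (log2 1.88, adjusted p = 0.227).

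ApoE knockout on HFD against WT on chow, both stresses together, differed in 129 macrophage genes. Abcg1 rose by 2.03 (SE 0.25), Plin2 by 1.38 (SE 0.20) and Lgals3, the galectin of lipid-laden macrophages, by 1.20 (SE 0.16). Isg15 (log2 2.65, SE 0.23), Ifit1 (log2 2.58, SE 0.21), Ifnb1 (log2 5.12, SE 0.64), Oasl1 (log2 3.59, SE 0.55) and the plasminogen activator Plau (log2 3.41, SE 0.53) rose. Slc40a1 (log2 −2.74, SE 0.29), the secreted phospholipase Pla2g2d (log2 −2.36, SE 0.42), Mmp9 (log2 −2.04, SE 0.34), Gas6 (log2 −1.71, SE 0.21) and the eosinophil-attracting chemokine Ccl24 (log2 −1.64, SE 0.23) fell. EdgeR called 83 higher and 46 lower, with the named genes at adjusted p from 0.000119 to 0.0401, and DESeq2 399. Interferon genes had 5 of 19 over all genes and 16 adjusted over the list alone (median 1.16; camera adjusted p = 3.86e-23, and adjusted p = 0.0911 with an estimated correlation), NF-kB genes 3 of 20 and 19 (median 1.79; adjusted p = 1.24e-17, and adjusted p = 0.165 with an estimated correlation), and lipid-associated genes 2 of 15 and 4 (median 0.44; adjusted p = 0.000266, and adjusted p = 0.143 with an estimated correlation). Of 15 resident-macrophage genes 1, Gas6, fell, and 5 were lower adjusted over the list alone (median −0.49; adjusted p = 1.18e-06, and adjusted p = 0.165 with an estimated correlation). Among markers of other cells, cardiomyocyte genes stood lower (median −0.63; adjusted p = 0.00894, and adjusted p = 0.502 with an estimated correlation) and T and NK effector genes higher (median 0.80; adjusted p = 0.000308, and adjusted p = 0.122 with an estimated correlation). The count was 3 without WT on chow replicate 1, 2 without its replicate 2, 30 without either ApoE knockout chow library, 195 without WT on HFD replicate 2 and 974 without ApoE knockout on HFD replicate 2; Apoe and Apoc4 were called each time. It was 26 in the 4 libraries alone and 67 without cluster 7, where 13 of the 37 named genes lost their call, among them Lgals3 (log2 0.98) and Mmp9 (log2 −1.86).

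The effect of HFD differed between the genotypes for 26 macrophage genes. Isg15 (log2 difference 2.39, SE 0.31), Bcl2a1b (log2 1.60, SE 0.20), Arl5c (log2 2.79, SE 0.38) and H2-Q6 (log2 1.89, SE 0.29) rose with HFD in the knockout relative to WT. In WT Arl5c stood at 13.1 and 17.0 CPM on chow and 8.28 and 7.32 CPM on HFD, and the mean of 2 libraries went from 24.6 to 15.8 CPM for H2-Q6, 82.0 to 75.2 CPM for Isg15 and 310 to 291 CPM for Bcl2a1b. The heat-shock genes Hspb1 (log2 −5.08, SE 0.61), Hspa1b (log2 −4.56, SE 0.48) and Hspa1a (log2 −3.81, SE 0.50) went the other way, as did Glrx5 (log2 −4.99, SE 0.74), Rab24 (log2 −4.18, SE 0.60) and Bri3 (log2 −3.99, SE 0.50). In the 2 ApoE knockout chow libraries Glrx5 stood at 47.6 and 49.8 CPM, Rab24 at 82.7 and 95.0 CPM and Bri3 at 209 and 249 CPM. In all other libraries, ApoE knockout on HFD included, they stood at 2.07 to 12.1, 4.56 to 21.4 and 13.7 to 59.5 CPM. The edgeR interaction test gave 4 positive and 22 negative genes of 10494, with these 10 at adjusted p from 0.0328 to 0.0480, and DESeq2 238. Relative to T cells of the same libraries, chosen after the data were seen, it called 8, all positive. In T cells themselves it called 21, all negative, and in dendritic cells 1 positive and 19 negative. In macrophages it called 0 without any one of the 4 chow libraries, 17 without WT on HFD replicate 2, 233 without its replicate 1 and 475 without ApoE knockout on HFD replicate 2. Without cluster 7 it called 46, but Arl5c (log2 1.65), Bcl2a1b (log2 1.02) and H2-Q6 (log2 1.60) were lost. Of 25 lists 5 were called, all positive and 0 with an estimated correlation, among them NF-kB genes (median 2.24, 0 of 20 over all genes, 18 adjusted over the list alone; adjusted p = 8.07e-27, and adjusted p = 0.253 with an estimated correlation) and cardiomyocyte genes, markers of another cell type (median 0.92; adjusted p = 0.00292, and adjusted p = 0.668 with an estimated correlation). The number of lists was 9 without WT on chow replicate 1 and 8 without WT on HFD replicate 1 or either ApoE knockout chow library.

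In dendritic cells 19 genes differed between the genotypes. Ccr7, the receptor that guides dendritic cells to lymph nodes, rose by 2.40 (SE 0.24), Plac8 by 1.61 (SE 0.23), S100a4 by 1.36 (SE 0.22), the interferon-induced Ifitm1 by 3.73 (SE 0.52) and Isg15 by 1.36 (SE 0.24). Dmkn rose by 4.48 (SE 0.58), whereas Mid1 (log2 −3.37, SE 0.51) and Rassf2 (log2 −0.94, SE 0.17) fell. EdgeR called 16 higher and 3 lower of 6825 genes (4 against 4 libraries, adjusted p up to 0.0489 for those named), and DESeq2 70. Interferon genes had 1 of 18 over all genes and 8 adjusted over the list alone (median 0.69; camera adjusted p = 5.90e-09, and adjusted p = 0.201 with an estimated correlation). Monocyte-derived macrophage genes had 2 of 10 and 6, with 1 lower adjusted over the list alone (median 0.67; adjusted p = 4.02e-06, and adjusted p = 0.201 with an estimated correlation). In the same libraries monocytes made up 5.58% of knockout and 1.27% of WT leukocytes, and Plac8 is among the genes that lead the monocyte cluster. The count was 2 without WT on HFD replicate 1, 5 without WT on chow replicate 1 and 12 without its replicate 2; Apoe and Ccr7 were called each time. Without the cluster of 44 cells led by Ccr7 itself, chosen after the data were seen, 11 genes passed and Ccr7 stood at log2 2.92 with an edgeR adjusted p of 0.0814. Isg15 (log2 1.37, adjusted p = 0.0549) and S100a4 (log2 1.30, adjusted p = 0.0634) also lost their call there.

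Averaged over the other factor, T cells gave few calls for diet or genotype and dendritic cells 0 for diet. In T cells edgeR called Apoe alone for genotype (log2 −8.65, SE 0.66, adjusted p = 4.79e-05, with 336 of 4237 genes at an unadjusted p under 0.05 and 20 called by DESeq2). The count was 2, 3, 5 and 4 without ApoE knockout on chow replicate 1, its replicate 2, ApoE knockout on HFD replicate 1 and WT on HFD replicate 2. For diet edgeR called 0 in T cells (387 at an unadjusted p under 0.05, 0 by DESeq2, 24 without WT on HFD replicate 2), with Tmem160 (log2 −1.98, adjusted p = 0.239) and Egr1 (log2 1.09, adjusted p = 0.439) among those nearest. In dendritic cells it called 0 (816 at an unadjusted p under 0.05, 22 by DESeq2, 6 without WT on HFD replicate 2), and Mndal, an interferon-inducible gene, came nearest (log2 1.04, SE 0.14, adjusted p = 0.0749). Klf2 (log2 −1.48, adjusted p = 0.183) and Mnda (log2 1.42, adjusted p = 0.183) did not pass. T cell lists were called 2 times of 20 for diet and 5 for genotype, and dendritic cell lists 7 times of 23 for each, 0 of them with an estimated correlation; MHC class II genes stood lower in knockout T cells (median −1.15, 0 of 6 over all genes, 4 adjusted over the list alone; adjusted p = 4.10e-09, and adjusted p = 0.248 with an estimated correlation). Resident-macrophage transcripts stood lower there too (median −0.79, 0 of 4, 2 adjusted over the list alone; adjusted p = 0.00698, and adjusted p = 0.259 with an estimated correlation). Macrophages, which express both lists, made up 47.1% of knockout and 70.0% of WT leukocytes. The comparisons of 2 with 2 libraries and the interaction were added for these classes after the data were seen. For HFD in the ApoE knockout edgeR called 83 genes of 4710 in T cells, 2 higher and 81 lower. In dendritic cells it called 114 of 7288, 20 higher and 94 lower (2 against 2 libraries). Without ApoE knockout on chow replicate 2 the counts were 46 and 42, and without ApoE knockout on HFD replicate 2 they were 359 and 417. For HFD in WT the counts were 0 and 0 in T and dendritic cells, for the knockout on chow 6 and 12, for the knockout on HFD 12 and 54, and for ApoE knockout on HFD against WT on chow 6 and 113. Lists in T cells numbered 4 for diet without ApoE knockout on chow replicate 1 and 2 for genotype without its replicate 2. In dendritic cells they numbered 3 for diet without ApoE knockout on chow replicate 2 or on HFD replicate 2, and 14 for genotype without WT on HFD replicate 2.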

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

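The tests of technical explanations in this part were chosen only after the results were seen, whereas the interaction of genotype with diet was a planned test.

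The response of macrophages to HFD differed between the genotypes for 26 genes by the edgeR interaction test, 4 positive and 22 negative, beside 21 negative genes in T cells and 19 negative and 1 positive in dendritic cells. The change with HFD in the ApoE knockout minus that in WT was 2.79 (log2) for Arl5c, 2.39 for Isg15, 1.89 for H2-Q6 and 1.60 for Bcl2a1b. It was −3.81 for Hspa1a, −3.99 for Bri3, −4.18 for Rab24, −4.56 for Hspa1b, −4.99 for Glrx5 and −5.08 for Hspb1. Bri3, Rab24 and Glrx5 stood high in the ApoE knockout chow libraries alone (209 and 249, 82.7 and 95.0, and 47.6 and 49.8 CPM). Elsewhere they reached at most 59.5, 21.4 and 12.1 CPM. The number of genes was 0 without any one of the 4 chow libraries, 17 without WT on HFD replicate 2, 233 without its replicate 1 and 475 without ApoE knockout on HFD replicate 2. Outside the named classes, 1433 cells lay in clusters called mixed, which carried the markers of another cell type together with macrophage transcripts. Unnamed clusters of 1441 and 411 cells were led by T or NK cell genes. Their C1qa, C1qb, C1qc and Csf1r counts stood at 0.63 and 0.67 of the macrophage level. Their median barcodes held 10292 and 6983 UMIs, beside 3402 in macrophages. Whether these barcodes held more than 1 cell was not tested. No gene comparison used the mixed or unnamed cells, although they counted as leukocytes in the class shares.

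HFD lowered 239 macrophage genes in the ApoE knockout (median log2 −1.78, quartiles −2.43 and −1.32), as part of 362 calls that became 0 without either ApoE knockout chow library, 188 without either WT chow library, and 166 or 1256 without ApoE knockout on HFD replicate 1 or 2. GC content and transcript length are argued against as the whole cause, because with offsets for both the median was −1.65 (quartiles −2.33 and −1.27) and 213 of the 239 genes were still called. A difference shared by the other cells of the same libraries fits the 148 of these genes that were tested in T cells, where the macrophage fold minus the T cell fold had a median of 0.00124 (quartiles −0.34 and 0.36). A difference between library preparations may also account for them, since 92.5% of the 239 genes were higher in replicate 2 than in replicate 1 of WT on HFD, which no treatment separates, although separate mice would differ in the same way. An effect of HFD on all cell types of the knockout heart stays open and was not tested.

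HFD raised 123 macrophage genes in the ApoE knockout (median log2 1.66, quartiles 1.26 and 2.33), among them interferon and NF-kB genes. For the 57 of these genes tested in T cells, the macrophage fold minus the T cell fold had a median of 0.929 (quartiles 0.59 and 1.62). The 57 were picked by their macrophage fold in the same libraries, which favours such a difference. A difference shared equally by both classes is argued against as the whole cause only for 18 of them. Those passed by edgeR over all genes tested in both classes. An effect that acts more on macrophages than on T cells was not tested apart from the diet. Transcription started by tissue dissociation cannot be told apart from an effect of the diet: the list of immediate early and dissociation genes had a median of 0.413, but its quartiles of −0.33 and 0.98 went both ways. The labels do not say whether the hearts of the groups were digested together. Between the replicates of WT on HFD, 29.3% of the 123 genes were higher in replicate 2 (median log2 −0.23, quartiles −0.68 and 0.05). These values cannot decide whether a difference between library preparations enters the higher genes, since the quartiles lie on both sides of 0. A response of knockout macrophages to the diet therefore stays open, as a hypothesis.

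Genotype changed 11 macrophage genes, Apoe included, against at most 1 in any other split of the 8 libraries. Only 1 of the 35 splits, the real one, gave as many, which argues against chance if the 8 libraries are independent. No label or file says that they are, and most other splits part the replicates of a group. The count does not exclude chance, since 1 of 35 is the least it allows and it was not adjusted over classes and factors. The 11 genes also hold the targeted Apoe with its neighbours Apoc1 and Apoc4. The number was 6 without either WT chow library, 5 without any one of the WT HFD or ApoE knockout chow libraries, 7 without ApoE knockout on HFD replicate 2 and 19 without its replicate 1. Of the 10 genes besides Apoe, 3 lie within 10 Mb of it, as do 153 of the 10232 genes tested (one-sided Fisher exact p = 0.000364), so DNA around the altered locus that came with the allele may account for those 3. The other 7 lie outside that window, so the test does not cover them, and DNA differences elsewhere in the genome were not tested. Loss of the ApoE protein stays open for both sets and was not tested apart from the allele.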

How the results depend on the processing

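The changes relative to T cells, the counts without the Ifnb1 or Ccr7 cluster, the GC and length offsets and the common UMI minimum were chosen after the data were seen, and the other alternatives before. The comparisons of 2 with 2 libraries and the interaction in T and dendritic cells were added after the data were seen as well. No named gene or class share past the threshold reversed. Counts of genes that moved by over 1.5 times are given as macrophage diet, genotype, HFD in WT, HFD in knockout, knockout on chow, knockout on HFD, knockout on HFD against WT on chow, and interaction. DESeq2 called 106, 133, 6, 563, 107, 312, 399 and 238, then 20 for T cell genotype and 22 and 70 for dendritic cell diet and genotype. For HFD in the knockout it called 52 in T cells, and the cause was not tested. Without the filter on low counts edgeR called 698, 515, 96, 1121, 313, 811, 1024 and 529, then 129 and 116 in T cells and 300 and 419 in dendritic cells for diet and genotype, and 238 and 479 in T and dendritic cells for HFD in the knockout. There the prior degrees of freedom became infinite, against 4.21 and 5.13 in macrophages with the filter, so that genes were no longer given a spread of their own. The numbers do not pair the samples (correlations of replicate differences between groups from −0.148 to 0.101), and with the replicate block edgeR called 6 for genotype, 47 for knockout on HFD and 6 for interaction. The mitochondrial limit of 20% gave 42 for interaction, and resolution 0.5 gave 1 for diet in dendritic cells. On only the 4 libraries of a comparison the counts were 205 for HFD in knockout, 352 for knockout on chow, 3 for knockout on HFD and 26 for knockout on HFD against WT on chow. There the spread came from those 4 libraries alone, and the counts moved both ways. Macrophage profiles of replicates correlated at 0.989 in WT on chow and 0.978 in ApoE knockout on chow. The correlation was 0.972 in WT on HFD and 0.944 in ApoE knockout on HFD. The spread shared over all 8 libraries does not allow for such differences between groups. Relative to T cells the counts were, in the same order, 34, 1, 27 and 13, and 8 for interaction, on the genes tested in both classes. Without the Ifnb1 cluster they were 204, 41, 25 and 67, with 46 for interaction and 1 for HFD in WT. With GC and length offsets knockout on chow gave 33, knockout on HFD 130, knockout on HFD against WT on chow 221 and interaction 80. Without the Ccr7 cluster dendritic cell genotype gave 11. With an estimated correlation camera called 0 lists in each comparison but macrophage genotype, which gave 3. Above the common UMI minimum 1 class share passed for diet and 5 for genotype. The cause of these changes was not tested unless named.

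In T and dendritic cells, counts that moved are given as HFD in WT, knockout on chow, knockout on HFD, knockout on HFD against WT on chow, and interaction. Without the filter on low counts they were 13, 61, 131, 158 and 95 in T cells and 46, 128, 463, 641 and 164 in dendritic cells. DESeq2 called 3 for knockout on chow and 18 for knockout on HFD against WT on chow in T cells, and 3 for HFD in WT, 23 for knockout on chow, 83 for knockout on HFD and 34 for interaction in dendritic cells. For knockout on HFD the replicate block gave 24 in T cells and 82 in dendritic cells, and for knockout on HFD against WT on chow 17 in T cells. With doublets kept T cells gave 6 and 1 for these comparisons, and dendritic cells 86 for the first. With the mitochondrial limit of 20% T cells gave 4 and 1, and dendritic cells 4 for knockout on chow, 26 for knockout on HFD and 32 for knockout on HFD against WT on chow. Leaving out 1 library gave, in the same order, 0 to 4, 1 to 34, 1 to 269, 1 to 270 and 0 to 84 in T cells and 0 to 7, 1 to 29, 15 to 464, 3 to 518 and 2 to 104 in dendritic cells. The highest came without WT on HFD replicate 2 for HFD in WT, without ApoE knockout on HFD replicate 1 for knockout on chow in T cells, and without its replicate 2 otherwise. The causes were not tested.

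Leaving out 1 library at a time, the lone library of a group being assumed to vary like the others, gave these lowest and highest counts of genes: macrophage diet 0 and 6 (without WT on HFD replicate 2), genotype 5 and 19 (ApoE knockout on HFD replicate 1), HFD in WT 0 and 7 (WT on HFD replicate 2), and HFD in knockout 0 (either knockout chow library) and 1256. Knockout on chow ranged from 2 to 83, knockout on HFD from 9 to 992, knockout on HFD against WT on chow from 2 to 974 and interaction from 0 to 475, and each of these highest counts, like 1256, came without ApoE knockout on HFD replicate 2. T cells gave 0 to 24 for diet and 1 to 5 for genotype, dendritic cells 0 to 6 and 2 to 27. For HFD in the knockout T cells gave 46 to 359 and dendritic cells 42 to 417, lowest without ApoE knockout on chow replicate 2 and highest without ApoE knockout on HFD replicate 2. Lists in macrophages ranged from 3 to 10 for diet, 8 to 14 for genotype, 2 to 8 for HFD in WT, 4 to 10 for HFD in knockout, 9 to 13 for knockout on chow, 4 to 12 for knockout on HFD, 8 to 15 for knockout on HFD against WT on chow and 4 to 9 for interaction. They ranged from 2 to 4 and 2 to 7 in T cells and from 3 to 9 and 6 to 14 in dendritic cells for diet and genotype. Class shares gave 0 to 0 for diet, 1 (without ApoE knockout on HFD replicate 2) to 6 (without ApoE knockout on chow replicate 2) for genotype and 0 to 2 (without ApoE knockout on chow replicate 1) for interaction. Over all alternatives, 136 named calls gave 2263 values, of which 1644 kept direction and call and 619 kept only the direction, and 30 genes named without a call gave 480, of which 56 passed. The 2 called shares gave 30 values, of which 29 kept the call, and the 22 others gave 330, of which 11 passed. Shares of classes with few cells are limited by depth, since NK cells numbered 4 to 25 per library.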

Other observations

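The comparison of macrophages with T cells and the tests of other splits were chosen only after the results were seen, whereas the gene lists and the tests within each class were planned.

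Relative to T cells of the same libraries, HFD changed 34 macrophage genes in the ApoE knockout, 31 higher and 3 lower. The macrophage fold minus the T cell fold was 4.68 for Cxcl10 (SE 0.48), a chemokine induced by interferon, 2.62 for the neutrophil-attracting chemokine Cxcl2 (SE 0.40), 2.70 for Tnf (SE 0.49), and 2.49 for Ccl4 (SE 0.43). Isg15 (log2 1.94, SE 0.32), the NF-kB subunit gene Rel (log2 1.62, SE 0.34) and Nfkbiz (log2 1.64, SE 0.35), a nuclear regulator of NF-kB targets, passed too. So did Id2 (log2 1.99, SE 0.33) and the heat-shock genes Hspa1a (log2 1.89, SE 0.39) and Dnajb1 (log2 1.82, SE 0.38), although in macrophages themselves Hspa1a fell (log2 −1.97, beside −3.78 in T cells) and Dnajb1 stood at −0.03. Ifi27 (log2 −1.28, SE 0.24), Dtnbp1 (log2 −1.79, SE 0.39) and Klf2 (log2 −1.54, SE 0.34) were lower. The edgeR adjusted p was at most 0.0435. Lyz2, C1qb and Cd14, transcripts typical of macrophages, are among the 34, and how far macrophage RNA in T cell barcodes enters these differences was not tested.

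Macrophage clusters differed in the genes that led them. Cluster 7, with 883 cells, held 555 Ifnb1 UMIs in 192 cells, and cluster 17, with 317 cells led by Ifit3, Ifit1, Rsad2 and Isg15, held 56 in 19 cells. Cluster 2, with 1917 cells led by Il1b, Cxcl2, Ccrl2 and Tnf, held 105 in 65 cells, cluster 5 held 37 in 23 cells, and cluster 0, with 2808 cells, held 3. Cluster 1 took 87.6% of its 2242 cells and cluster 3 took 78.2% of its 1899 cells from WT on HFD replicate 1, so neither describes a group. Cluster 7 took 71.0% of its cells from ApoE knockout on HFD replicate 1, so it too rests largely on 1 library.

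Resident-macrophage transcripts stood lower in dendritic cells with HFD, with 0 of 13 genes past the threshold over all genes and 8 lower adjusted over the list alone (median log2 −0.95; camera adjusted p = 3.12e-09, and adjusted p = 0.607 with an estimated correlation). For genotype the same list had 2 lower adjusted over the list alone (median −0.76; adjusted p = 6.72e-07, and adjusted p = 0.404 with an estimated correlation). The dendritic cell clusters 9, 16 and 27 carried C1qa, C1qb, C1qc and Csf1r counts at 0.24, 0.33 and 0.27 of the macrophage level. How far macrophage RNA in their barcodes enters these list differences was not tested. MHC class I genes, which display peptides to cytotoxic T cells, had 6 of 12 higher adjusted over the list alone and 0 over all genes in knockout dendritic cells (median 0.35; adjusted p = 6.88e-05, and adjusted p = 0.404 with an estimated correlation). In knockout T cells, T and NK effector genes had 4 higher and 1 lower of 15 adjusted over the list alone and 0 over all genes (median 0.63; adjusted p = 1.16e-05, and adjusted p = 0.248 with an estimated correlation). Cluster 19, a part of the T cells led by genes such as Ccl5, Ifng and Cd8b1, differed in size between libraries. In the knockout it held 66 of 197 and 9 of 87 T cells on chow and 79 of 268 and 25 of 118 on HFD. In WT it held 12 of 108 and 15 of 87 on chow and 15 of 120 and 26 of 111 on HFD. How far this enters the list difference was not tested.

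Every other way to split the 8 libraries into 4 and 4 was tried for the average effects, 35 ways with the real one. If the 8 libraries are independent, chance is argued against for the genotype effect on dendritic cell genes, with 19 genes in the real split and at most 7 in any other. No label or file says that they are. The split with 7, WT on chow and ApoE knockout on HFD against the rest, kept the replicates of each group together, and most others did not. Chance is not excluded, since 1 of the 35 gave as many, the least this count allows. For genotype in T cells the count cannot decide, with 1 gene against a highest of 2 (4 of the 35). That gene was the targeted Apoe, at 345 to 1564 CPM in the WT libraries and 0 to 8.42 CPM in the knockout libraries. These values argue against chance for Apoe. For diet the real split gave 0 genes in macrophages (1424 at an unadjusted p under 0.05, 106 by DESeq2), T cells (387 and 0) and dendritic cells (816 and 22). All 35 splits therefore had to give as many, and the count of splits cannot decide for diet. The highest other split gave 6, 35 and 9 genes, and in macrophages and dendritic cells it was the split by genotype. The 35 T cell genes came from the split of WT on chow replicate 1, WT on HFD replicate 2 and both ApoE knockout chow libraries against the rest. This may reflect a structure of the samples, which was not tested.

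For gene lists chance cannot be excluded for either factor in any class. In macrophages diet gave 9 lists in the real split and at most 11 in another (5 of the 35 gave as many), and genotype 9 and 12 (13 of the 35). In T cells diet gave 2 and 6 (19 of the 35), and genotype 5 and 8 (9 of the 35). In dendritic cells diet gave 7 and 11 (19 of the 35), and genotype 7 and 16 (17 of the 35).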
